A study of Homo sapiens with 6 samples.

How the data were processed

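Total RNA of MDA-MB-231 breast cancer cells was sequenced as 3 control and 3 CCDC12 knockdown libraries. Per the labels' protocols, RNA with an integrity number of at least 7 went into libraries made with the TruSeq Stranded mRNA kit, which keeps polyadenylated RNA and marks the strand. Per the submitters' processing notes, the tools were Trimmomatic, HISAT2 and HTSeq and the genome build was hg38. Their versions, the gene annotation, the strand setting of the counting and whether reads were paired are not given in the sources used here. The deposited values are raw gene counts, 1 table per library with gene symbols, and the authors' counts were used as deposited. Reads that match several places can be dropped or assigned to 1 copy by such counting, so genes with near-identical copies carry uncertain counts, and without a stated strand setting genes that overlap on opposite strands cannot be told apart with certainty.

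Groups and replicate numbers were taken from the sample titles. Total counts lay between 38772338 and 39803562 per library. A count of 0 allows up to 3 counts, or between 0.0754 and 0.0774 CPM (counts scaled to library size) in a library, and this floor covers counting error only. Libraries of one group differed by more than counting noise (chi-square per degree of freedom between 3.04 and 3.57), so no library was counted as a repeat of another. This excess does not show that they were separate cultures. Libraries of different groups gave between 78.0 and 81.3. The first principal component of log2 CPM held 64.6% of the variance and separated the groups, and the second held 9.74%.

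Tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, with factors between 0.988 and 1.01, and the groups were compared with edgeR's quasi-likelihood test with the group as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM values and their SD were computed from the counts with TMM-scaled library sizes. Gene lists were tested with limma's camera on log2 CPM (prior count 2) at a preset correlation of 0.01, with an estimated correlation and with fry, and adjusted over the 25 lists. The lists are activated spliceosome and PRPF19 complex, SR and hnRNP regulators, snoRNA host and decay-sensitive transcripts, G2/M and mitosis, DNA replication and E2F targets, p53 and growth arrest, BCL2 family and caspases, epithelial markers, mesenchymal markers, matrix proteases with integrins and adhesion, type I interferon response, NF-kB and inflammatory cytokines, integrated stress and unfolded protein response, heat shock, immediate early genes, TGF-beta and YAP targets, cholesterol synthesis and SREBP targets, glycolysis and hypoxia, nuclear oxidative phosphorylation, ribosomal proteins, mitochondrially encoded transcripts, histones, and markers of luminal epithelium, of leukocytes and of fibroblasts and endothelium.

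The lists, the tests between the groups and of the lists, their alternatives and the rule for naming genes were fixed before the data were examined, while several tests of explanations were chosen later, as the closing section states. The rule names CCDC12 and RBM47, the 12 largest increases and the 12 largest decreases among called genes with a mean log2 CPM of at least 2, a gene name and no overlap between the groups, the 5 most abundant called genes in each direction, and up to 4 called members of each list with the smallest p. Other members are named in the report for the 2 near-identical heat shock genes and UPF1, which were chosen after their values were seen. A few genes that the rule names are not reported here.

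GENCODE release 29 on GRCh38, the same assembly as hg38, gave positions, lengths, GC content, introns, 3' UTRs, overlaps and shared 51-base words. Of the 21941 symbols 18155 (82.7%) matched it, as did 95.3% of the tested genes. The alternatives were median-of-ratios scaling, total-count scaling, DESeq2, limma-voom, no filter on low counts, a mean of at least 1 CPM, each library left out in turn and the replicate number as a block. The procedure was tested on simulated data for this comparison with 14173 genes. It recovered 60% of 50 genes changed by 1.2-fold, 73.5% at 1.5-fold, 84% at 2-fold and 100% of 47 genes at 4-fold. It called 10 of 13977 genes that were not changed, which made up 6.06% of its calls. Few genes were changed in the simulation, while 62.0% of the tested genes were called in the data, so these rates need not hold there. Splicing was not analysed here.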

Results

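Messenger RNA was measured by stranded RNA sequencing in MDA-MB-231 cells, an established line of triple-negative breast cancer cells with a mesenchymal shape. The 6 libraries fell into 2 groups, 3 control libraries and 3 libraries in which CCDC12 had been knocked down with a short hairpin RNA. CCDC12 is a protein found in the activated spliceosome. The title of the series names RBM47, an RNA-binding protein, as a gene whose splicing depends on CCDC12, and the comparison asks which genes differ in level when CCDC12 is lowered. The values were gene counts, which show the level of a gene and not how its transcripts were spliced. Total counts were 39803562, 39013454 and 39470905 in the control libraries and 38772338, 38794801 and 39207349 in the knockdown libraries. Between 18315 and 18514 genes had a count above 0 in a library, and 14320 of the 21941 listed genes were tested. The labels do not say whether the replicates were separate cultures, or whether the numbered knockdown samples carried the same hairpin, so p-values measure only the spread between these libraries, which may be technical.

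CCDC12 was lower in each of the 3 knockdown libraries than in any control library. The gene lies on chromosome 3 from 46921726 to 46982010, on the minus strand of GRCh38, and is annotated as protein coding. Its counts were 847, 773 and 791 in the control libraries and 438, 439 and 454 in the knockdown libraries. The mean fell from 20.6 ± 0.806 to 11.3 ± 0.154 CPM (read counts scaled to library size; SD, n = 3 each), and the knockdown level was 54.7% of control. The log2 fold change was -0.87 with a standard error (SE) of 0.078, and the adjusted p was 9.59e-17 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

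RBM47 was higher in each of the 3 knockdown libraries than in any control library. It lies on chromosome 4 from 40423267 to 40630875, on the minus strand of GRCh38, and is annotated as protein coding. Its counts were 334, 365 and 331 in the control libraries and 859, 814 and 750 in the knockdown libraries. The mean rose from 8.81 ± 0.555 to 20.5 ± 1.51 CPM (SD, n = 3 each), or to 233% of control. The log2 fold change was 1.22 with an SE of 0.083 (edgeR, adjusted p = 1.29e-22). Counts per gene hold no measure of exon use, so the splicing of RBM47 was not analysed here.

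**Figure D1:**
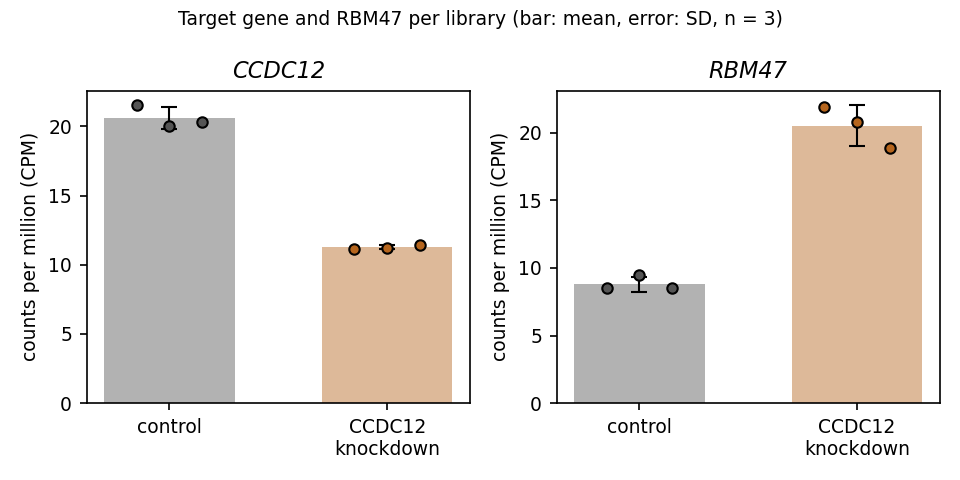
Level of CCDC12 and RBM47 in CPM (vertical axis) in the control and CCDC12 knockdown libraries. Points are the 3 libraries of each group, bars the mean and error bars the SD; CCDC12 fell from a mean of 20.6 to 11.3 and RBM47 rose from 8.81 to 20.5.

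Knockdown was accompanied by changes in a large part of the measured genes, most of them small. The mucin genes MUC5B and MUC5AC, the collagen-binding integrin gene ITGA10, the transcription factor genes FOS and SOX4 and the growth factor receptor gene PDGFRB were among the largest increases. The protease inhibitor gene SERPINB2, the long non-coding RNA UCA1, the metalloprotease genes ADAMTS1, ADAMTS9 and ADAMTS6 and the cytokine and receptor genes LTA, IL24 and IL7R were among the largest decreases. In edgeR's quasi-likelihood test 8880 of 14320 genes (62.0%) had an adjusted p under 0.05, 4463 higher and 4417 lower, and 9290 had an unadjusted p under 0.05. The median size of the change among the 8880 genes was 1.27-fold. By at least 2-fold, 688 genes were higher and 277 lower, counts that were 433 and 143 when only genes with a mean of at least 1 CPM were tested. All knockdown libraries lay on the same side of all control libraries in 9326 tested genes (65.1%), and 438 called genes had overlapping groups. Chance gives 10% only if all libraries are independent, which the labels do not state. The share therefore does not tell an effect of the knockdown from another difference between the groups.

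MUC5B, which encodes a gel-forming mucin, rose from 0.248 ± 0.061 to 13.0 ± 0.758 CPM (SD, n = 3 each), a log2 fold change of 5.70 with an SE of 0.19 (edgeR, adjusted p = 3.05e-41). Its sister mucin gene MUC5AC rose from 1.25 ± 0.284 to 8.06 ± 0.167 CPM. ITGA10 rose from 7.02 ± 0.990 to 43.7 ± 0.856 CPM and FOS, a subunit of the AP-1 transcription factor, from 4.28 ± 0.765 to 22.5 ± 0.547 CPM. SOX4 had a log2 fold change of 2.36, DNM3 of 2.32, PDGFRB of 2.08, VWA1 of 2.07, PADI1 of 2.06, MEGF9 of 2.03 and C1R, a protease of the complement cascade, of 1.98. PLLP was at 401% of control. Of the exon bases of PLLP, 19.9% overlap ARL2BP on the opposite strand, which had 12701 counts against 2040 for PLLP, and the strand setting of the counting is not given in the sources used here, so the value of PLLP is uncertain. C1R shares 11.4% of its exon bases with C1RL on the same strand.

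SERPINB2, which encodes an inhibitor of urokinase, fell from 61.9 ± 1.19 to 8.68 ± 0.593 CPM (SD, n = 3 each), a log2 fold change of -2.83 with an SE of 0.063 (edgeR, adjusted p = 1.29e-53). UCA1 fell from 15.9 ± 0.648 to 2.56 ± 0.391 CPM and ADAMTS1, a secreted metalloprotease gene, from 29.7 ± 0.865 to 4.88 ± 0.086 CPM. IL7R, the interleukin 7 receptor gene, fell from 66.8 ± 1.01 to 18.3 ± 1.11 CPM, and the cytokine gene IL24 from 120.4 ± 0.900 to 39.2 ± 3.16 CPM. The log2 fold change was -1.98 for LTA, which encodes lymphotoxin alpha, -1.86 for CHAC1, -1.79 for ADAMTS9, -1.78 for ADAMTS6, -1.72 for FGF5 and -1.66 for LNCOG.

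**Figure D2:**
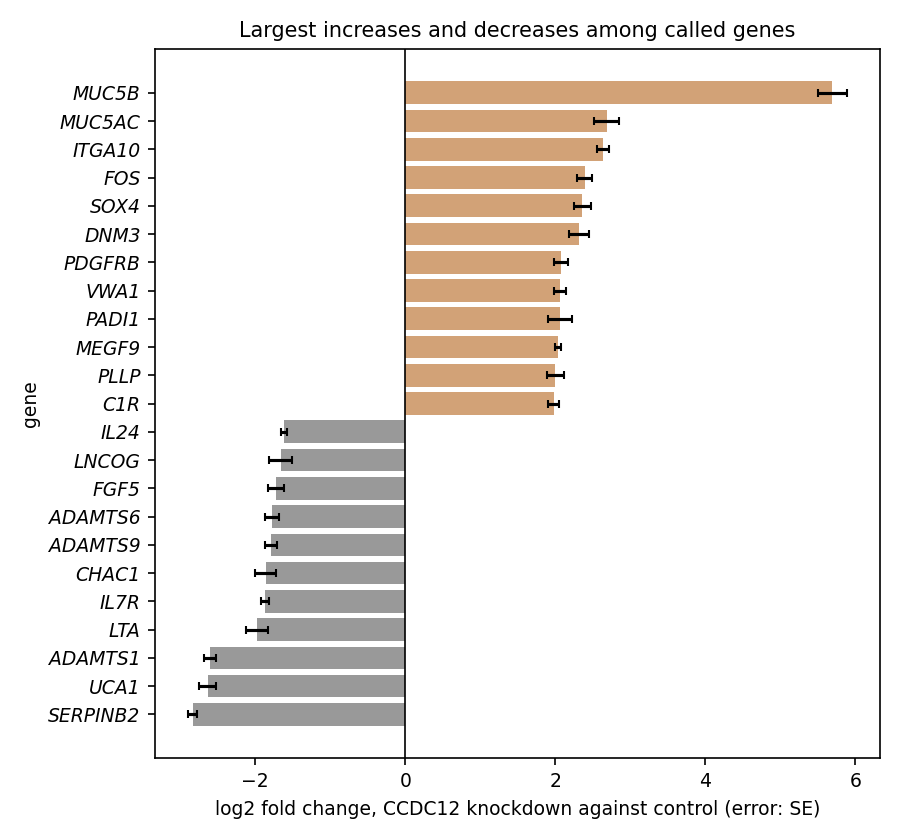
Log2 fold change of CCDC12 knockdown against control (horizontal axis) for the 12 largest increases and 11 of the 12 largest decreases that met the naming rule; error bars are the SE. MUC5B stands apart at 5.70, and the decreases run from -2.83 for SERPINB2 to -1.62 for IL24.

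Among the most abundant genes that passed the test the changes were small. The mitochondrial genes COX3, ND2, CYTB and ND5 and the iron storage gene FTH1 were higher, FTH1 at 117% and ND2 at 110% of control. The mitochondrial genes COX1, ND4, COX2 and ND1 and the translation elongation factor gene EEF1A1 were lower, COX1 at 89.0% and EEF1A1 at 94.1% of control. The call of ND4 was lost when libraries were scaled by their total counts alone (adjusted p = 0.198, edgeR), and those of CYTB and ND5 without a filter on low counts and when control replicate 2 was left out (adjusted p = 0.159 and 0.0538 without that library). CYTB also lost its call without knockdown replicate 1 (adjusted p = 0.104) and without knockdown replicate 2 (adjusted p = 0.0522). Mitochondrial genes took between 7.70% and 7.90% of all counts in the control libraries and between 7.77% and 7.81% in the knockdown libraries.

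Of the 25 gene lists fixed beforehand, limma's camera test with a preset correlation between genes of 0.01 called 5 lower and 1 higher. None of the 6 calls held with an estimated correlation, whose adjusted p is given beside each list. In 19 lists the counts of higher and lower members adjusted over the list alone equal those over all genes tested, and in the other 6 lists both are given. The fry test, which does not compare a list with other genes, called 24 lists for members that moved on balance one way and 25 for members that changed in either direction.

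**Figure D3:**
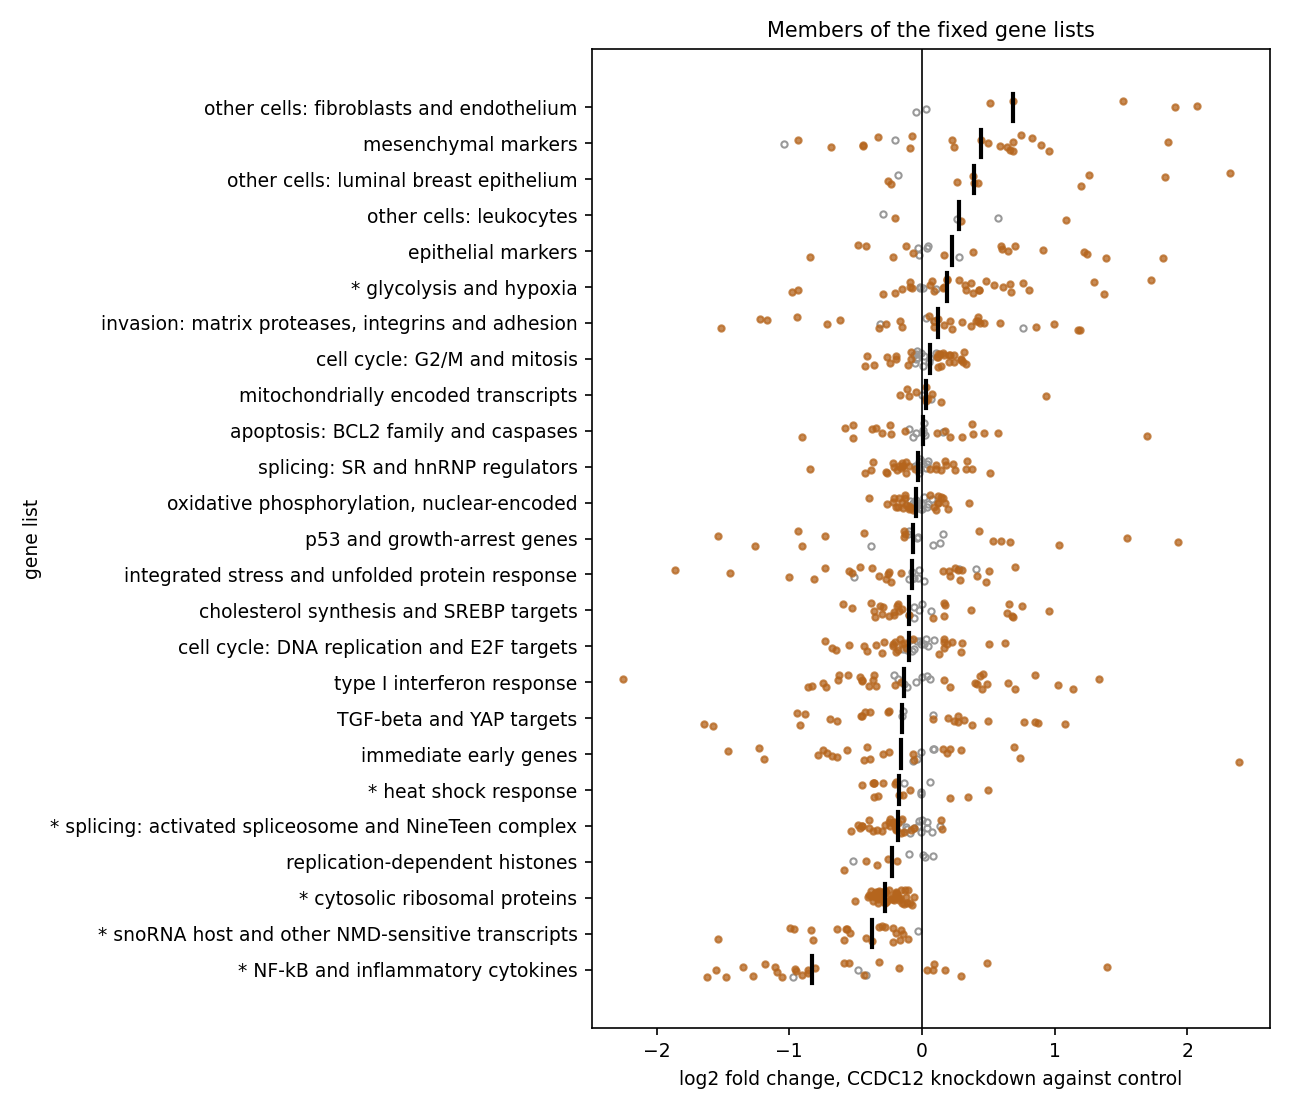
Log2 fold change of each tested member (horizontal axis) of the 25 fixed gene lists (vertical axis). Filled points passed the edgeR test over all genes, open points did not, black bars are list medians and asterisks mark the 6 lists called by camera with the preset correlation; the medians run from -0.83 for the inflammatory cytokines to 0.69 for the fibroblast and endothelial markers.

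Most inflammatory cytokine and NF-kB pathway genes were lower after knockdown. Of 30 tested members 20 fell and 7 rose (7 higher and 23 lower adjusted over the list alone), 9 fell by at least 2-fold, and the median member was at 56.2% of control. The chemokine gene CXCL8 had a log2 fold change of -1.10 (SE 0.016), PTX3, a soluble pattern recognition protein, of -1.19 (SE 0.018) and IL24 of -1.62 (SE 0.039). CSF1, the macrophage colony stimulating factor, went the other way at 1.40 (SE 0.017). The list was lower in camera (adjusted p = 4.04e-05), with an adjusted p = 0.0712 with an estimated correlation.

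All 52 tested genes of cytosolic ribosomal proteins fell, by small amounts. The median member was at 82.6% of control, and the log2 fold changes ran from -0.50 to -0.06. RPS2 had a log2 fold change of -0.50, RPL35 of -0.41, RPL6 of -0.38 and RPL8 of -0.34. The list was lower in camera (adjusted p = 7.22e-14), with an adjusted p = 0.0646 with an estimated correlation. After correction for a trend on transcript length, GC content, exon number and mean level the median log2 fold change was -0.14 in place of -0.28.

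Of 23 snoRNA host genes and other transcripts sensitive to nonsense-mediated decay, 22 fell and none rose. The members include non-coding hosts of small nucleolar RNAs as well as the decay factors themselves, such as UPF1. GADD45A, a growth arrest gene, had a log2 fold change of -1.54, SNHG1 of -0.99, ZFAS1 of -0.84 and GAS5 of -0.64. Of the exon bases of ZFAS1, 11.1% overlap ZNFX1 on the opposite strand. The list was lower in camera (adjusted p = 2.46e-07), with an adjusted p = 0.0646 with an estimated correlation.

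Genes for the activated spliceosome and the PRPF19 complex, the assembly in which CCDC12 is found, were lower more often than higher. Of 41 members 26 fell, 2 rose and 13 did not pass the test, and the median member was at 88.1% of control. RBM22 had a log2 fold change of -0.54, SF3A3 of -0.45, SF3B4 of -0.40 and EFTUD2, a GTPase of the U5 particle, of -0.40. The list was lower in camera (adjusted p = 2.53e-04), with an adjusted p = 0.0692 with an estimated correlation. The SR and hnRNP regulators of splicing were not called (adjusted p = 0.303), with 12 of 40 higher, 18 lower and a median log2 fold change of -0.03, which was 0.00218 with total-count scaling. Among them PTBP1 was at -0.43, SRPK1 at -0.38, RBM25 at -0.37 and HNRNPC at -0.27.

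Genes of glycolysis and the hypoxia response were higher as a list. Of 36 members 24 rose and 8 fell, and the median member was at 114% of control. CA12, a membrane carbonic anhydrase, had a log2 fold change of 1.73, NDRG1 of 0.81, the lactate exporter gene SLC16A3 of 0.61 and the glycolytic enzyme gene ENO1 of 0.39. The list was higher in camera (adjusted p = 3.33e-03), with an adjusted p = 0.10 with an estimated correlation.

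Heat shock genes were slightly lower. Of 19 members 12 fell and 3 rose, among the latter the near-identical genes HSPA1A and HSPA1B. The constitutive chaperone genes HSPA8, HSP90AB1 and HSPD1 each had a log2 fold change of -0.36 and HSP90AA1 of -0.37. The list was lower in camera (adjusted p = 0.0403), with an adjusted p = 0.265 with an estimated correlation. The call was also lost when only genes with a mean of at least 1 CPM were tested (adjusted p = 0.0672) and without knockdown replicate 1 (adjusted p = 0.0516).

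Neither the epithelial nor the mesenchymal markers were called as a list in the main test. Of 22 epithelial markers 11 rose and 6 fell (median log2 fold change 0.22, adjusted p = 0.191), with RBM47 itself at 1.22, the keratin gene KRT7 at 0.91, the tight junction gene CLDN4 at 0.60 and the desmosome gene DSP at -0.42. Of 23 mesenchymal markers 14 rose and 7 fell (median 0.45, adjusted p = 0.115), with S100A4 at 0.96, COL5A1 at 0.90, LOXL2 at 0.59 and FN1 at 0.45. The mesenchymal list was called higher with limma-voom (adjusted p = 0.0208, between 0.0208 and 0.265 over its alternatives). The list of matrix proteases, integrins and adhesion genes was not called either (median 0.12, adjusted p = 0.128), but was with limma-voom (adjusted p = 0.0208, between 0.0208 and 0.282 over its alternatives). Of its 33 members 19 rose and 10 fell (19 and 11 adjusted over the list alone), with the laminin gene LAMA5 at 1.19 and the integrin gene ITGB5 at 199% of control, and with the urokinase gene PLAU at -0.72.

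Cell cycle lists held members that moved both ways. Of 42 genes of DNA replication and E2F targets 10 rose and 19 fell (median -0.10, adjusted p = 0.142), with RRM2 at -0.73, CDC6 at -0.65, UHRF1 at -0.55 and the helicase gene MCM6 at 0.50. Of 40 genes of G2/M and mitosis 18 rose and 10 fell (18 and 11 adjusted over the list alone; median 0.06, adjusted p = 0.505), with BUB3 at -0.43, CDC20 at -0.41, CKS1B at -0.36 and TOP2A at 0.24. Of 10 replication-dependent histone genes none rose and 5 fell (median -0.22, adjusted p = 0.121), with H2BC11 at -0.59, H2BC4 at -0.42, H2BC12 at -0.34 and H1-2 at -0.19. The library kit keeps polyadenylated RNA, so histone transcripts that are not polyadenylated are largely missed and their levels were not measured.

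Of 24 p53 and growth-arrest genes 7 rose and 9 fell (adjusted p = 0.505). The cell cycle inhibitor gene CDKN1A had a log2 fold change of -0.93 and PLK2 of -1.26, and the list's median was -0.07 while its mean was 0.01. Of 27 genes of the BCL2 family and caspases 9 rose and 10 fell (adjusted p = 0.505), with the median at 0.01 (between -0.04 and 0.04 over the alternatives) and the test leaning lower. PMAIP1 and BMF, both activators of apoptosis, were at -0.90 and 1.70, the survival gene MCL1 at -0.52 and CYCS at -0.52.

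Growth factor response genes were mixed. Of 28 immediate early genes 7 rose and 16 fell (8 and 16 adjusted over the list alone; median -0.16, adjusted p = 0.0813), with MYC at -1.19, DUSP5 at -0.74, FOSL1 at -0.71 and CCN1 at -0.64, against 2.39 for FOS. This list was called lower without a filter on low counts (adjusted p = 0.0445) and with limma-voom (adjusted p = 0.0208), with a range from 0.0208 to 0.282 over its alternatives. Of 28 targets of TGF-beta and YAP 12 rose and 13 fell (13 and 13 adjusted over the list alone; median -0.15, adjusted p = 0.505), with ANKRD1 at -0.92 and the tissue factor gene F3 at -0.88. Of 39 type I interferon response genes 14 rose and 17 fell (median -0.13, adjusted p = 0.505), with ISG15 at -0.73, IFIT3 at -0.63, IFIT2 at -0.62 and IFITM3 at 0.44.

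Of 36 genes of the integrated stress and unfolded protein responses 11 rose and 15 fell (median -0.07, adjusted p = 0.346). The amino acid transporter genes SLC3A2 and SLC7A5 were at -0.81 and -0.53, the chaperone gene HSP90B1 at 0.42 and DDIT4 at 0.70. Of 33 genes of cholesterol synthesis and SREBP targets 11 rose and 16 fell (12 and 18 adjusted over the list alone; adjusted p = 0.458). Its median was -0.10 and its mean 0.02, camera leaned lower and fry higher. The genes SREBF1, FADS2 and SCD, of which FADS2 and SCD encode fatty acid desaturases, were at 0.96, 0.68 and 0.64.

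Nuclear genes of oxidative phosphorylation were not called as a list. Of 43 members 11 rose and 17 fell (median -0.05, adjusted p = 0.392), with ATP5MC1 at -0.40, CYC1 at -0.26 and ATP5PB at -0.22. Of the exon bases of ATP5PB, 10.3% overlap WDR77 on the opposite strand. Of 13 mitochondrially encoded transcripts 7 rose and 4 fell (median 0.03, adjusted p = 0.629), with COX1 at -0.17, COX2 at -0.11, ND2 at 0.14 and ND6, the message encoded on the light strand, at 0.94. Since the strand setting of the counting is not given, the counts of ND6 may include RNA from the other strand, and its value is uncertain.

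Markers of other cell types were measured beside these lists. Of 15 markers of fibroblasts and endothelium only 7 passed the filter on low counts. Of these 7 tested markers 5 rose and none fell (median 0.69, adjusted p = 0.0544), with PDGFRB at 2.08, PECAM1 at 1.91 (from only 0.718 to 2.71 CPM), COL1A1 at 0.69 and EGFL7 at 0.51. This list was called higher under 5 alternatives, total-count scaling (adjusted p = 0.0497), limma-voom (0.0430) and without control replicate 2 (0.0462), knockdown replicate 2 (0.0261) or knockdown replicate 3 (0.0438), and its highest adjusted p over the alternatives was 0.265. Of 11 tested markers of luminal breast epithelium 8 rose and 2 fell (median 0.39, adjusted p = 0.0710), with AGR2 at 1.83 (from only 1.26 to 4.48 CPM), KRT19 at 0.39, ERBB2 at 0.26 and ERBB3 at 230% of control, and this list was called higher without control replicate 2 (adjusted p = 0.0468, up to 0.265 over its alternatives). Of 6 leukocyte markers 2 rose and 1 fell (median 0.28, adjusted p = 0.505), with CD74 at 1.09, LAPTM5 at 0.30 and CD68 at -0.20. Of the 125 named genes 17 share over 20% of their 51-base words with another annotated gene, among them CD68 with 92.4%, RPL6 with 71.2%, H2BC12 with 70.6%, RPS2 with 52.1% and COX1 with 50.7%, and their counts are uncertain to that extent.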

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

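No alternative was added after the results were seen. Of the 8880 called genes between 8126 and 8862 were called again under each alternative, each in the same direction; the filter of a mean of at least 1 CPM tested 8434 of them and kept 8376. DESeq2 called 4242 genes higher and 4255 lower, and left 3 genes without an adjusted p. Total-count scaling called 4865 higher and 3987 lower and moved the median of all genes to 0.03 on the log2 scale. Requiring a mean of at least 1 CPM tested 12415 genes in place of 14320 and called 8507 in place of 8880. It gave 433 genes at least 2-fold higher in place of 688, and 143 at least 2-fold lower in place of 277. Many of the 2-fold calls therefore lay in genes below that mean. The number of lists called higher was 2 with total-count scaling, 4 with limma-voom and 0 with an estimated correlation, and lay between 1 and 3 when a library was left out (3 without control replicate 2, 2 without knockdown replicate 2 or 3); the cause was not tested. The number called lower was 0 with an estimated correlation and 6 with limma-voom or without a filter on low counts, which added the immediate early genes; it lay between 4 and 5 when a library was left out. The estimated correlation gave the highest adjusted p of each of the 6 called lists, and the lowest over the alternatives were 5.98e-29 for ribosomal proteins, 4.69e-10 for snoRNA hosts, 2.59e-07 for cytokines, 8.06e-06 for the spliceosome, 3.21e-04 for glycolysis and 1.69e-03 for heat shock. Values of named genes kept their call and direction in 1592 instances and lost the call in 7, all in ND4, CYTB and ND5. Values of lists kept theirs in 305, gained a call in 10 and lost it in 9. No named gene changed direction and no list did so in camera, but the medians of 2 lists that were not called changed sign, from -0.0461 to 0.00218 for SR and hnRNP regulators and from -0.0432 to 0.0419 for the BCL2 family and caspases. Same-numbered libraries did not deviate together (correlations -0.119, -0.155 and 0.0131), so the numbers do not pair the samples; with the replicate number as a block 4440 genes were higher and 4418 lower, and the heat shock list was not called (adjusted p = 0.0765, between 1.69e-03 and 0.265 over its alternatives). At this depth genes near the floor of 3 counts carry little information.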

Other observations

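The tests of gene families, of scaling, of spread against mean count, of even against odd counts per library, of shared 51-base words and of the AU-rich element within the list and in genes changed by at least 2-fold, and the bootstrap interval of the ribosomal protein median and how it is set against the bounds were chosen after results had been seen; the other tests were written beforehand.

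Grouped by the stem of their symbols, 16 of 167 gene families were lower and 3 higher after CCDC12 knockdown in camera with the preset correlation, and 0 were called with an estimated correlation. Of 54 symbols that begin with EIF, mostly translation initiation factors, 42 fell and 6 rose, with EIF3J at 50.7% of control, and the adjusted p of the stem was 7.24e-06. All 10 UTP genes, which act in processing of ribosomal RNA, fell, with UTP4 at 54.2% of control, and the adjusted p of the stem was 2.96e-04. Of 31 symbols that begin with POLR, mostly RNA polymerase subunits, 25 fell and 2 rose, with POLR1G at 49.4% and POLR1B at 60.2% of control, and the adjusted p of the stem was 8.27e-05. Of 51 symbols that begin with MRPL, mostly mitochondrial ribosomal proteins but with non-coding neighbours among them, 35 fell and 1 rose, with an adjusted p of the stem of 1.11e-05. The other stems called lower were RPL, RPS, MRPS, DDX, NUP, TIMM, SNHG, PSMD, NAA, EXOSC, TAF and SF, and the elongation factor stem EEF was not called (6 of 13 lower, adjusted p = 0.0827).

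The 3 stems called higher were PCDHB, DENND and COL. Of 12 protocadherin beta genes 9 rose and none fell, with PCDHB11 at 282% of control, and the adjusted p of the stem was 6.68e-03. Of 25 collagen genes 13 rose and 2 fell, with COL18A1 at 230% of control, and the adjusted p of the stem was 0.0288. Beside them 5 of 7 tested markers of fibroblasts and endothelium rose and none fell (median log2 fold change 0.69, adjusted p = 0.0544, and 0.265 with an estimated correlation), and COL1A1 belongs to both groups. Of 17 symbols that begin with DENND, among them the antisense RNA DENND3-AS1, 12 rose and 1 fell, with an adjusted p of the stem of 8.77e-03. With an estimated correlation the adjusted p was 0.278 for PCDHB, 0.409 for COL and 0.354 for DENND, and 0.204 for EIF and MRPL, 0.219 for POLR and 0.229 for UTP. The families and the named examples were chosen after their values were seen.

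The first pattern is the small joint decrease of ribosomal protein genes. The choice among the 3 scalings tried does not account for it, since the median was at most -0.243 (log2) under each. TMM and total-count scaling differed by only 0.0325 (log2) between the groups, so they could not have brought the median near 0. The comparison therefore does not address a scaling error that all 3 share. A trend on length, GC content, exon number and mean level, which held 8.45% of the variance across genes, took the median from -0.28 to -0.140 (95% bootstrap interval -0.165 to -0.080), with 43 of 52 members still below 0. The bounds set beforehand were for the median itself, above -0.05 for the trend as the whole cause and below -0.10 for ruling it out. The median lay below -0.10. Its interval, which was added later, excludes -0.05 but reaches past -0.10. It resamples genes as if they were independent and is not a spread between libraries. On this stricter reading the trend and an effect of the knockdown cannot be told apart here. Of the 52 genes 3 share over 50% of their 51-base words with another gene, and the median of the other 49 was -0.27.

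The second pattern is the decrease of the list of inflammatory cytokines and NF-kB genes, for which a shorter message life or poorer splicing of genes with many introns may be candidate explanations. Genes with the AU-rich nonamer in the 3' UTR lay -0.0330 (log2) from genes without after correction (permutation p = 0.0073, 10000 permutations) and -0.0318 without the genes of the list (permutation p = 0.0107), between the bounds set beforehand, while 13 of 30 list members had the element and lay -0.305 from the other 17 (permutation p = 0.529, 95% bootstrap interval -0.686 to 0.520), so these tests do not decide. Among genes with an annotated 3' UTR and outside the list, 24 of 154 lower by at least 2-fold had the element (15.6%) against 50 of 591 higher by at least 2-fold (8.46%, Fisher's exact p = 0.0146, two-sided). These shares were not corrected for 3' UTR length, GC content or mean level, so they do not decide on the first explanation either. Genes with 10 or more introns lay 0.0485 above intronless genes (permutation p = 0.0463), opposite to the direction written beforehand for a loss of splicing capacity. Counts per gene do not show splicing, so poorer splicing need not lower them. The rise was not steady, since the corrected median was -0.033 without introns, -0.115 with 1 to 2, -0.043 with 3 to 5, 0.000714 with 6 to 9, -0.00233 with 10 to 19 and 0.0446 with 20 or more. The intron comparison was made over genes at large and gives no intron numbers for the list members, so it does not decide why the list fell. An effect of the knockdown by another route stays open and untested.

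The third pattern is the spread between libraries of one group. It exceeded Poisson noise by a similar factor at every level, a mean ratio of 3.39 at counts of 50 to 200 and 4.01 above 5000, a quotient of 1.18, where variation between separate cultures would raise it with the count. In genes that share no 51-base word the control median was 2.11 against 0.693 from Poisson noise, so shared reads do not account for the bulk. Counting both mates of a pair predicts an excess of even counts, and 56.3% of counts from 2 to 40 were even, between the bounds set beforehand. That range starts and ends on an even number and 51.3% of its numbers are even, so part of the excess is built in. The excess sat at low counts, with a mean of 462 genes at a count of 4 against 350.5 at 3 and 322 at 5. It was not seen from 6 to 40 (ratio to odd neighbours between 0.967 and 1.02 over libraries), as it also would not be if some pairs were counted once. Counting of both mates therefore stays open as a source. The widest spread was sought among 10191 genes with a mean count between 50 and 5000. Pseudoautosomal genes, which have an identical copy on the Y chromosome, were compared without that copy, so some can count as sharing no word. Of the 50 genes with the widest spread 16 (32%) share over 50% of their words with another gene, against 275 of 10141 others (2.71%, Fisher's exact p = 2.66e-13, two-sided). Reads assigned to near-identical copies differently between libraries could give such an excess.

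The cancer-testis gene XAGE1A, chosen after its values were seen, had counts of 21, 27 and 10 in the control and 20, 12 and 1633 in the knockdown libraries, so its call (edgeR, adjusted p = 1.27e-10) rests on knockdown replicate 3. All of its 51-base words occur in another gene (100%).

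The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share of splits under 0.1. The real split gave 4463 genes higher, 4417 lower, 688 at least 2-fold higher and 277 at least 2-fold lower, and the highest of the other splits gave 0 genes on each measure, so 1 split of 10 reached each value. For lists, the real split called 1 higher and 5 lower, and the highest of the other splits called 4 in one direction. Counted in either direction, 10 of the 10 splits called at least 1 list, as many as the real split called higher, and 1 called 5. Every other split had both control and knockdown libraries on each side, in unequal numbers. Part of the group difference thus stayed between its sides, and the rest became spread within them. In the other splits lists were called only lower where the first side held mostly control libraries, and only higher where it held mostly knockdown libraries. The other splits therefore do not show how many genes or lists chance alone would call.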
